A study of Zea mays with 2 samples.

How the data were processed

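Leaf RNA of maize (Zea mays, cultivar Sugar 75) at the V5 stage was sequenced in 2 libraries, 1 from untreated plants and 1 from plants treated with a seaweed extract. Per the labels, each library was made from a pool of 3 independent samples and was analysed with 2 technical replicates, and the series concerns drought. Whether both pools came from plants under drought, and how the technical replicates entered the deposited values, is not given in the sources used here. RNA was isolated with the NucleoSpin RNA Plant kit and libraries were prepared with Illumina protocols, per the labels' protocols. The label of the treated library names it only as the sample, and the series text states that 1 library is control and 1 is treated.

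Per the submitters' processing notes, the tools were cutadapt 1.8.1, TopHat2 2.1.0, Bowtie2 2.2.6, Picard 1.115, Cufflinks 2.2.1 and Cuffdiff without a version, with no role or order given. The genome build is not given in the sources used here. The library tables deposited by the authors hold, per the file headers, 1 FPKM value (fragments per kilobase of gene, scaled to library size) per gene with the lower and upper bound of its interval and a quantification status, for 39634 genes in each library. Per the file headers the tables also pair the gene identifiers with protein names, family descriptions and reference gene numbers. The 4 tables of the authors' own comparison hold, per the file headers, a log2 fold change, a p-value, a q-value and a significance flag for the genes listed as higher or lower. Their largest p-values are 0.00995 in the shorter lists, and 0.0499 and 0.05 in the longer ones, and these values are the authors' own. The test score of the authors' comparison was taken as deposited and is not reported, and 8 columns with FPKM values in these tables were not used, because their names match no library's label. In the authors' deposited table a test of 1 library against 1 compares those libraries, not the conditions.

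FPKM values keep no library totals, so the depth was read from the deposited intervals. An interval whose distance from the value to its upper bound is 2 times the value divided by the square root of the fragment number gives an implied fragment number, and 71.8% of the 6200 control genes below 5 implied fragments and 71.5% of the 6010 treated genes came out whole within 0.01 fragments. Over the 4774 genes that were whole in both libraries, 1 fragment was worth 1.24 times as much FPKM in the treated library (5th to 95th percentile 1.19 to 1.30), so that the control library was the deeper one. Since not all low values came out whole, no count test was run. The median distance from the value to the upper bound was 20.2% of the value in the control library and 21.6% in the treated one for genes between 1 and 10 FPKM, and 8.65% and 9.75% for genes at 10 FPKM or more. These intervals cover the quantification of 1 library and not the spread between plants or pools.

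The 181 genes on the plastid and mitochondrial chromosomes, 57 and 124, are listed at 0 in both libraries, and a further 13 genes have a status other than OK and are listed at 0. An exact 0 can therefore be a missing estimate, and no plain fold was computed against it, but such genes stayed in the log2 ratios and counts. For each gene with at least 1 FPKM in at least 1 library, log2((treated + 1)/(control + 1)) was computed on the values as deposited. This scale understates the difference of low genes. Genes with a log2 ratio of at least 1 were counted as higher and those of at most -1 as lower in the treated library. The control was at 0 for 24 of the genes counted as higher, and the treated library for 41 of those counted as lower. With 1 library per group there is no replicate check, no p-value was computed, and each difference describes these 2 libraries.

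Before the data were examined, 35 gene lists were fixed as patterns on gene symbols and descriptions. For each list with at least 5 measured members the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile below 2.5 or above 97.5 is described as outside the central 95% of random lists, which is a description of these libraries and not a test of the treatment. The lists share members, and percentiles under alternatives rest on 2000 random lists. The genes named follow a rule that was also fixed then. It takes the 12 largest log2 ratios of each direction among annotated genes at 10 FPKM or more with intervals that do not overlap and status OK. It adds the 2 members of each list with the largest absolute log2 ratio at 10 FPKM or more (up to 4 where a list is described at length), the 5 genes with the highest mean, and the 3 highest annotated genes of each direction in the authors' deposited lists. Genes named outside this rule are marked as such.

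Reference gene symbols came from the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only, which matched 23902 of the 39634 identifiers. Loci are given as the deposited tables place them, with starts moved by 1 base to count from 1. The tables count starts from 0, since end minus start was a multiple of 3 for 58.0% of the 3019 gene models named after clones (identifiers starting with AC) and end minus start plus 1 for 21.7%. A total of 69 measured loci on the nuclear chromosomes carry the annotation of a plastid- or mitochondrion-encoded gene and no nuclear reference gene. They are called organelle-type loci here, a grouping made after seeing the data.

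Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data over 27936 genes, with fragment noise at a depth averaged over the 2 libraries and a small assumed spread between them. All of the 50 genes at 10 FPKM or more simulated at each of 3-fold up, 3-fold down, 4-fold up and 4-fold down were recovered (100%). Of 3265 unchanged genes at 10 FPKM or more 0% were called. These changes exceed the 2-fold limit, so the check says nothing of genes near that limit, of lower genes or of the real spread between pools. Of 40 simulated lists of 30 unchanged genes 1 lay outside the central 95%, and of 40 shifted lists 40 did. Alternatives covered the pseudocount, the minimum, the scaling, the status, the threshold, the intervals, the bins and the limits on the authors' lists. Matching lists by description only and leaving out the organelle-type loci were chosen after seeing the data.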

Results

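The leaf transcriptome of maize plants treated with a seaweed extract, a preparation of marine algae applied to crops, was compared with that of untreated plants in a series on drought. Each group had 1 library, made from a pool of leaves, and values are FPKM as deposited. The control library listed 14983 of 39634 genes at 1 FPKM or more and the treated library 15568, with 3070 and 3793 genes at 10 FPKM or more. The summed FPKM was 233809 in the control and 230054 in the treated library, and the 10 highest genes of each took 18.1% and 12.5% of it. Fragment numbers implied by the intervals placed the treated library at the lower depth, with 1 fragment worth 1.24 times as much FPKM as in the control. A value set against another is that of the treated library against the control's, and where values are joined by 'and' the control's comes before. There were no replicates, so every difference below is one between 2 libraries with intervals that cover quantification error only.

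Genes of the photosystems, of chlorophyll synthesis and of carbon fixation had lower median ratios in the treated leaf library than random lists of genes. Glutathione S-transferases, flavonoid synthesis and a joint list of senescence and chlorophyll breakdown had higher ones, but so did cytosolic ribosomal proteins, a control list. Without a minimum FPKM, which lets silent genes into the lists, only the photosystem, chlorophyll synthesis and ribosomal protein lists among these stayed outside the central 95% of random lists. Of 16272 genes at 1 FPKM or more in at least 1 library, 604 (3.71%) were higher in the treated library by a log2 ratio of at least 1 and 410 (2.52%) were lower. Among the more abundant genes, at 100 FPKM or more in at least 1 library, 20 were higher and 55 were lower. Of all 604 higher and 410 lower genes, 581 and 391 had intervals that did not overlap between the libraries. These genes were chosen for a large difference, so the missing overlap adds little. Higher genes made up 59.6% of the 2 directions on the deposited scale. The median gene was itself 0.22 higher in the treated library on the log2 scale (0.27 without the pseudocount over 14279 genes at 1 FPKM or more in both). With the libraries centred on that median gene, 332 genes were higher and 552 were lower, so that higher genes made up 37.6%. Medians of gene lists are therefore also given after centring.

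Among annotated genes outside organelle-type loci, the largest differences to the lower side included light-harvesting, polyamine and defence genes. GRMZM2G414192 and GRMZM2G120619, which encode chlorophyll a/b binding proteins of the light-harvesting antenna, had 59.9 (95% interval 55.9 to 64.0) and 28.1 (26.1 to 30.2) FPKM in the control and 0.27 (0 to 0.56) and 0.091 (0 to 0.22) FPKM in the treated library. An arginine decarboxylase gene (GRMZM2G374302, chromosome 4, 144835678 to 144840927), whose enzyme opens a route of polyamine synthesis, had 0.40 FPKM (0.19 to 0.61) against 37.9 FPKM (35.7 to 40.1). An agglutinin-domain gene (GRMZM2G134264) had 0.19 FPKM against 24.1, and AC193786.3_FG005, annotated as an achaete-scute homolog, 0.084 against 24.8 FPKM. The glucosidase gene glu2 (GRMZM2G008247, chromosome 10, 37754967 to 37759771), annotated to release the benzoxazinoid defence compound DIMBOA from its glucoside, had 15.8 FPKM (14.4 to 17.2) in the control and was listed at 0 in the treated library.

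On the higher side, the annotated genes with the largest differences outside organelle-type loci included genes of cutin synthesis, amino acid and isoprenoid metabolism and a receptor-type kinase, while 8 loci that are not organelle-type, most of them unannotated, were higher by a log2 ratio of at least 3. GRMZM2G083195, annotated as glycerol-3-phosphate 2-O-acyltransferase 6, an enzyme type that makes cutin precursors, had 34.3 FPKM (32.1 to 36.6) in the treated library and 3.84 FPKM (3.28 to 4.41) in the control, 8.93-fold higher. An aminotransferase gene (GRMZM2G153536) was 7.04-fold higher at 32.0 against 4.55 FPKM, and a dehydrodolichyl diphosphate synthase gene (GRMZM2G054803) was 6.60-fold higher at 25.2 against 3.83 FPKM. The lectin-domain protein kinase gene GRMZM2G397889 had 16.3 FPKM against 2.19, 7.45-fold higher. A chlorophyll a/b binding protein gene, GRMZM2G018627, had 32.4 FPKM (29.5 to 35.4) in the treated library and 0.13 FPKM (0 to 0.32) in the control. It lies on chromosome 1 at 247758733 to 247760445, near GRMZM2G414192 at 247727655 to 247729365, and both match the same 2 reference genes, so the split of reads between them is uncertain.

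Among annotated genes, organelle-type loci made up 6 of the 12 largest differences to the lower and 7 of the 12 to the higher side. On the lower side were 2 ferredoxin-domain loci (GRMZM5G852325, 4.58 against 494 FPKM, and GRMZM5G896790, 0.17 against 23.5 FPKM), 2 loci of chloroplast NADH dehydrogenase subunits (GRMZM2G354804, 0.95 against 79.8 FPKM, and GRMZM2G070573, 1.74 against 68.6 FPKM), the ATP synthase MI25 locus GRMZM2G470035 (0.67 against 35.5 FPKM) and the psbE locus GRMZM2G062044 (listed at 0 in the treated library and at 33.1 FPKM in the control). On the higher side were the ycf4 and cemA loci GRMZM5G883075 and GRMZM2G360833, which lie side by side on chromosome 6 and had 0.65 and 2.47 FPKM in the control and 53.5 and 95.4 FPKM in the treated library. The other higher ones were an RNA polymerase locus (GRMZM2G126177, 103 against 2.98 FPKM), rps7 (GRMZM5G880319, 28.0 against 0.15 FPKM), cob (GRMZM2G112030, 20.9 against 0.44 FPKM), another psbE locus (GRMZM2G108467, 130.1 against 10.8 FPKM) and ndhJ (GRMZM2G404025, 24.2 against 2.99 FPKM). Values at such loci are uncertain, because the genes of the organelle chromosomes are all listed at 0 and reads of near-identical copies can be placed at any of them.

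Organelle-type and unannotated loci also had the highest means of the 2 libraries. The unannotated locus GRMZM2G157517 had 5691 FPKM in the control and 5011 in the treated library, and the ferredoxin-domain locus GRMZM2G096792 had 5801 and 4469 FPKM. GRMZM2G586702, an unannotated locus on chromosome 9, had 6964 and 2710 FPKM. The psbK-type locus GRMZM2G015355 had 5329 and 2278 FPKM, and the ycf9 locus GRMZM2G374263 had 4340 and 2996 FPKM.

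Genes of the photosystems and their antenna proteins, which capture light and drive electron transport, were lower in the treated library as a group. Of 72 measured members, 42 were lower and 3 were higher, and 66 lay below the median of all genes. Their median log2 ratio was -1.24 (interquartile range -1.91 to -0.32), 1.46 below the median of all genes and below each of the 10000 random lists. Centring moved the list's median to -1.51, with 52 lower and 3 higher. The 62 members that are not organelle-type loci, a split made after seeing the data, had a median of -1.32 with 40 lower and 2 higher (-1.57 with 48 and 2 after centring), while the 10 organelle-type loci had a median of -0.18 with 2 lower and 1 higher (-0.44 with 4 and 1 after centring).

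Photosystem I subunits, light-harvesting proteins and photosystem II proteins each had lower medians, by a split made after seeing the data. Among 16 photosystem I subunit genes, 14 were lower and none was higher, with a median of -1.44 (-1.70 with 15 lower after centring). Light-harvesting chlorophyll a/b binding protein genes numbered 24, of which 16 were lower and 2 higher (median -1.32, and -1.58 with 20 lower and 2 higher after centring), and 10 of the 22 photosystem II and oxygen-evolving protein genes were lower and none higher (median -0.95, and -1.21 with 13 lower after centring). GRMZM2G033885 (Lhcb4), which encodes the minor antenna protein CP29, had 838 FPKM (802 to 874) in the control and 150.4 FPKM (142 to 159) in the treated library, a log2 ratio of -2.47. The chlorophyll a/b binding protein 6 gene GRMZM2G092311 had 277 against 729.5 FPKM (log2 ratio -1.39), and the photosystem I subunit N gene GRMZM2G080107 had 237 against 690.5 FPKM (-1.54). Not every abundant member differed: CAB1 (AC207722.2_FG009) had 1419 against 1530.4 FPKM and psb3 (GRMZM2G174984), a photosystem II 10 kDa polypeptide gene, 636 against 640.7 FPKM, both named after their values were seen. Antenna proteins form families of near-identical genes, so the values of single members are less certain than the group's.

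**Figure D1:**
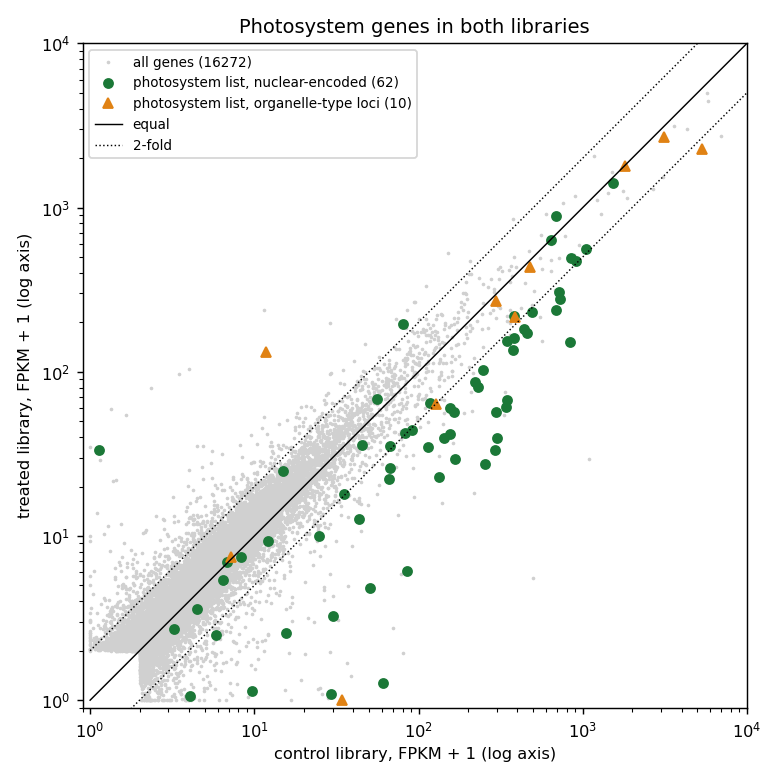
FPKM + 1 of each gene in the control library (x axis) and the treated library (y axis), both log axes, for 16272 genes (grey) with the 62 photosystem members that are not organelle-type loci as green circles and the 10 organelle-type loci as orange triangles; the solid line marks equal values and the dotted lines a 2-fold difference. Of all 72 members, 42 had a log2 ratio of at most -1 and 3 of at least 1.

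The chlorophyll synthesis list also had a lower median in the treated library. Of its 8 measured members, 3 were lower by a log2 ratio of at least 1 and none was higher (4 lower after centring), 1 had a positive log2 ratio but all 8 lay below the median of all genes, and the median of -0.80 (-1.02 after centring) lay below all random lists. Geranylgeranyl diphosphate reductase (GRMZM2G105644), which makes the phytol tail of chlorophyll, had 47.3 FPKM (44.8 to 49.9) against 141 FPKM (137 to 145). Protochlorophyllide reductase (GRMZM2G073351) had 15.4 against 42.5 FPKM. The magnesium chelatase subunit gene CHLI (GRMZM2G419806) had 14.4 against 27.4 FPKM.

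The carbon fixation list had a smaller shift to the lower side. Of 38 members of the C4 and Calvin cycles, 4 were lower and none was higher, 13 had positive log2 ratios but 30 lay below the median of all genes, and the median of -0.27 lay below all random lists. After centring, 8 were lower and the median was -0.51. The Rubisco small subunit genes GRMZM2G113033 and ssu1 (GRMZM2G098520) had 154 against 566 FPKM and 36.1 against 160.5 FPKM. A pyruvate phosphate dikinase gene, PPDK2 (GRMZM2G097457), had 7.72 against 38.2 FPKM, and its annotation does not show whether it acts in the C4 cycle. The glyceraldehyde-3-phosphate dehydrogenase gene gpa1 (GRMZM2G337113) had 315 against 681 FPKM. Among 5 enzymes typical of mesophyll or bundle sheath cells, the cell types between which C4 photosynthesis is divided, the median was -0.68 with 1 lower (-0.94 with 2 lower after centring) at percentile 2.62 of random lists, too close to the limit of 2.5 to place, since most alternatives put it below. The bundle sheath markers ssu1, RCA1 (GRMZM2G162200, 255 against 488 FPKM) and me3 (GRMZM2G085019, 591 against 944 FPKM) and the mesophyll marker pep1 (GRMZM2G083841, 1262 against 1747 FPKM) were all at the lower value in the treated library.

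The joint list of senescence and chlorophyll breakdown genes had a higher median than random lists. Of 18 members, 5 were higher and 2 were lower, with a median of 0.54 at percentile 99.8, or 0.30 with 4 higher and 2 lower after centring. Pheophytinase (GRMZM2G109070), which removes phytol from pheophytin during chlorophyll breakdown, had 49.5 FPKM (46.4 to 52.6) against 14.9 FPKM (13.6 to 16.2), 3.32-fold higher. A senescence regulator gene (GRMZM2G351318) had 11.4 against 2.43 FPKM, and see2a (GRMZM2G081626), a legumain protease gene, 19.3 against 9.49 FPKM. The list's largest difference was in the other direction, in pao1 (GRMZM2G034152), with 22.2 FPKM (20.6 to 23.8) in the control and 1.98 FPKM (1.43 to 2.53) in the treated library. Its symbol matched the list's pattern, but it encodes a polyamine oxidase and not a chlorophyll breakdown enzyme.

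Genes commonly linked to drought showed small median differences as groups. Among 28 late embryogenesis abundant (LEA) and dehydrin genes, whose proteins protect cells during water loss, none was higher and 4 were lower. Their median was 0.06 at percentile 3.82, inside the central 95% of random lists. After centring it was -0.16 with 5 lower at percentile 2.40, and with a minimum of 5 FPKM -0.20 at percentile 0.10, both below the central 95%. The dehydrin genes GRMZM2G373522 and GRMZM2G147014 had 9.44 against 19.7 FPKM and 12.3 against 18.6 FPKM, while the LEA genes GRMZM2G472248 and GRMZM2G106906 had 16.6 against 9.14 FPKM and 18.9 against 11.3 FPKM. Abscisic acid genes, 97 in number, had a median of 0.28 (0.044 after centring) at percentile 88.7, with 4 higher and 3 lower (2 and 3 after centring). The list took in protein phosphatase 2C genes by their family description, which does not show that each acts in this pathway. The receptor gene PYL7 (GRMZM2G144224) had 10.04 FPKM in the control and 2.14 FPKM in the treated library, and the protein phosphatase 2C gene GRMZM2G443509, of a family that includes negative regulators of the pathway, 11.8 and 31.7 FPKM. The pattern of the DREB and CBF list matched only 1 gene at 1 FPKM or more, and genes of this type under other names would be missed. That gene, GRMZM2G006745, had 9.22 and 10.3 FPKM with overlapping intervals (7.97 to 10.5 and 8.82 to 11.8). Its log2 ratio was 0.15, and -0.093 after centring.

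Detoxification genes differed by family. Glutathione S-transferases, which conjugate glutathione to reactive compounds, had 7 higher and no lower genes among 44, with a median of 0.49, above all random lists, and 6 higher with a median of 0.27 after centring. The genes GRMZM2G028821, gst30 (GRMZM2G044383) and gst31 (GRMZM2G475059) had 52.0, 19.4 and 18.2 FPKM in the treated library and 10.4, 4.77 and 6.36 FPKM in the control, the latter 4.07- and 2.86-fold higher. Reactive oxygen scavenging genes, 43 in number, had 3 higher and none lower, and a median of 0.09 at percentile 3.69, inside the central 95% of random lists. After centring the median was -0.15 at percentile 2.45, below the central 95%, where a minimum of 5 FPKM also put it (median 0.060). The ascorbate peroxidase genes POD1 (GRMZM2G137839) and GRMZM2G054300 had 121 against 56.1 and 99.2 against 46.2 FPKM. After centring no member of this list was higher by a log2 ratio of 1 and 1 was lower. Of 6 class III peroxidase genes 2 were lower and none higher (median -0.19, -0.38 after centring, percentile 1.79), a place below the central 95% that was lost for the 5 members matched by description alone, with PER42 (GRMZM2G126261) at 10.7 against 23.0 FPKM and GRMZM5G843748 at 22.4 against 11.5 FPKM.

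Chaperone, aquaporin, osmolyte and ion transport genes had medians close to that of all genes, except for the osmolyte list. Of 221 heat shock protein and chaperone genes 8 were higher and 2 lower (median 0.19, -0.0090 with 6 higher and 3 lower after centring, percentile 12.4). The DnaJ-type genes GRMZM2G144997 and GRMZM2G158117 were 4.88- and 4.62-fold higher, at 14.9 against 3.06 and 13.1 against 2.84 FPKM. Aquaporins, the water channels, had 2 higher and none lower of 21 (median 0.20, 0.018 after centring, percentile 50.1), with pip1b (AC209208.3_FG002) at 48.2 against 23.5 FPKM and tip4a (GRMZM2G103945) at 140.5 against 69.7 FPKM, and after centring none was higher and 1 was lower. Osmolyte synthesis genes had a median of -0.06 (-0.24 after centring) at percentile 0.020, but 0.16 at percentile 16.2 with a minimum of 5 FPKM, and 2 of 35 were higher and 1 lower (2 and 3 after centring). One of the higher members, tps1 (GRMZM2G049538, 44.6 against 10.2 FPKM), is a terpene synthase gene caught by its symbol. The galactinol synthase gene gols3 (GRMZM5G872256, 84.9 against 42.0 FPKM) had a log2 ratio of 0.998, just short of the limit of 1. Without the members matched by symbol, 30 remained with a median of -0.12 at percentile 0, none of them higher or lower by a log2 ratio of 1, and after centring the median was -0.31 with 2 lower. Ion and potassium transport genes had 2 of 71 higher and none lower (median 0.23, 0.048 after centring, percentile 56.6), and the sodium/hydrogen exchanger gene GRMZM2G037342 had 38.9 against 19.5 FPKM and the GORK-type potassium channel gene GRMZM2G310569 14.1 against 8.17 FPKM.

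The flavonoid list lay above the central 95% of random lists and the phenylpropanoid list within it. Of 26 phenylpropanoid and lignin genes 4 were higher and 1 lower (median 0.36, 0.12 with 3 higher and 1 lower after centring, percentile 93.6), and only a minimum of 5 FPKM put the list outside, at percentile 97.85. A hydroxycinnamoyltransferase gene (AC215260.3_FG003) had 16.8 against 4.60 FPKM and the cinnamate 4-monooxygenase gene GRMZM2G010468 10.9 against 3.59 FPKM. Flavonoid synthesis genes had a median of 0.58 at percentile 99.98, which was 0.33 after centring, although only 1 of 21 passed a log2 ratio of 1. That gene was the anthocyanidin reductase gene GRMZM2G097854 at 12.5 against 4.67 FPKM. The cytochrome P450 gene CYP92C6 (GRMZM2G139467), annotated as a flavonoid 3'-monooxygenase, had 15.0 against 7.77 FPKM.

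Sugar, cell wall and lipid genes differed in both directions, while the counts of nitrogen genes depended on the scaling. Among 43 genes of sucrose and starch metabolism and sugar transport 1 was higher and 4 were lower, with a median of 0.01 at percentile 0.345 that became -0.19 after centring. A beta-amylase gene (GRMZM2G007939) had 12.1 against 36.3 FPKM and an invertase-type gene (GRMZM2G139300) 11.0 against 25.6 FPKM. The cell wall list held 417 genes (10 higher, 5 lower, median 0.23, 0.022 with 5 higher and 6 lower after centring, percentile 70.1), most of them clone names caught by its symbol pattern. Matched by description alone it held 37 genes, 3 higher and 3 lower. The median of those was -0.0027 at percentile 0.39, and -0.15 after centring. A cellulose synthase-like gene (GRMZM2G074546) had 14.3 FPKM in the control and 0.15 FPKM in the treated library, and the BTB/POZ domain gene GRMZM2G130505, caught by its clone name, 3.67 and 16.4 FPKM. Lipid transfer, wax and cutin genes had 1 of 30 higher and 2 lower (median 0.30, 0.12 after centring, percentile 86.9), and the lipid-transfer protein gene GRMZM2G031354 had 30.2 against 91.2 FPKM. The starch synthase gene GBSSIIa (GRMZM2G008263), caught through its annotation as a waxy protein, had 110.4 against 179.7 FPKM. Its log2 ratio was -0.70 (-0.96 after centring), short of the limit. Nitrogen uptake and assimilation genes had 4 of 39 higher and none lower (median 0.16, -0.031 with 3 higher and 2 lower after centring, percentile 24.6). The cytosolic-type glutamine synthetase family was split, with gln5 (GRMZM2G036464) at 28.5 against 12.4 FPKM and gln3 (GRMZM2G050514) at 24.2 against 42.3 FPKM, while gln1 (GRMZM2G098290), annotated as the chloroplast form, had 6.74 against 14.0 FPKM, and gln3 and gln1 passed a log2 ratio of 1 to the lower side only after centring. GRMZM5G863076, annotated with a nitrate and iron dehydrogenase family, had 16.1 against 5.79 FPKM.

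Among hormone genes, single members stood out more than the lists. The cytokinin dehydrogenase gene CKX10 (GRMZM2G348452, chromosome 1, 207708925 to 207713476), whose enzyme type degrades cytokinin, had 31.5 FPKM (29.1 to 33.8) in the control and 2.098 FPKM in the treated library and was the only one of 10 cytokinin genes to pass a log2 ratio of 1 in either direction (median 0.27, 0.075 after centring, percentile 66.8). In the jasmonate list of 32 genes, opr5 (GRMZM2G087192), an oxophytodienoate reductase gene by its symbol, was 4.72-fold higher at 40.3 against 8.55 FPKM. The gene lox6 (GRMZM2G040095), annotated as a 9S-lipoxygenase, was lower at 9.72 against 43.7 FPKM. Neither description shows that the gene acts in jasmonate synthesis, the theme of the list. That list's median was 0.0082 at percentile 0.86, with 1 higher and 1 lower, and -0.15 with 1 higher and 3 lower after centring, but 0.13 at percentile 15.6 with a minimum of 5 FPKM. Auxin response genes had 2 of 65 higher and 1 lower (median 0.30, 0.089 after centring, percentile 93.1), and PINY (GRMZM2G050089) had 11.2 against 6.21 FPKM and ARF6 (GRMZM2G017187) 16.6 against 9.64 FPKM. Ethylene genes had 1 of 38 higher and 1 lower (median 0.20, -0.0056 with none higher and 2 lower after centring, percentile 36.5). EREB204 (GRMZM2G061487) had 14.9 against 7.67 FPKM and ACO15 (GRMZM2G166639) 7.36 against 13.7 FPKM, both short of a log2 ratio of 1 before centring. Of 7 gibberellin genes 2 were higher and 1 lower (median 0.32, 0.092 with 1 higher and 1 lower after centring, percentile 73.1), and the receptor gene GRMZM2G173630 had 12.2 against 8.11 FPKM.

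Defence genes went both ways. Of 51 pathogenesis-related and defence genes 6 were higher and 9 were lower, and the median was -0.0064 at percentile 0.050, or -0.26 with 3 higher and 10 lower after centring. A Bowman-Birk protease inhibitor gene (GRMZM2G007928) had 2.17 FPKM (1.43 to 2.91) against 20.3 FPKM (18.3 to 22.3) in the control, and a thaumatin-family gene (GRMZM2G402631) 2.91 against 16.0 FPKM. A chitinase-related gene (GRMZM2G099092) and a glucan endo-1,3-beta-glucosidase gene (GRMZM2G111324) were 6.52- and 4.88-fold higher at 11.6 against 1.78 and 14.0 against 2.88 FPKM.

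Transcription factor lists had medians close to or above that of all genes. WRKY factors, many of which act in stress responses, had 3 of 33 higher and 1 lower (median 0.46, percentile 99.96, 0.29 with 1 higher and 1 lower after centring), but the 6 at 5 FPKM or more were at percentile 71.4, and WRKY1 (GRMZM2G398506) had 12.6 against 7.94 FPKM. Basic leucine zipper (bZIP) factors had 2 of 22 higher and none lower (median 0.44, 0.25 after centring, percentile 99.5), but the 5 at 5 FPKM or more were at percentile 28.5 and the 9 matched by description alone had a median of 0.19 (-0.0023 after centring) at percentile 45.9. The member bZIP52 (GRMZM2G174284) had 11.8 against 6.97 FPKM. NAC factors had 2 of 15 higher and none lower (median 0.21, -0.030 after centring, percentile 48.9), with NAC1 (GRMZM2G347043) at 23.2 against 16.8 FPKM and AC196475.3_FG005 at 10.2 against 8.65 FPKM (log2 ratio 0.21, -0.030 after centring). MYB factors had 5 of 94 higher and 2 lower (median 0.14, -0.052 with 4 higher and 3 lower after centring, percentile 9.40). The member with the largest absolute difference at 10 FPKM or more was glk1 (GRMZM2G026833, chromosome 9, 2711381 to 2713815), of a family that activates photosynthesis genes. It had 39.4 FPKM (37.1 to 41.8) in the control and 15.7 FPKM (14.2 to 17.2) in the treated library. AC204212.4_FG001, named MYBR78 but annotated with a DnaJ-type family, had 35.2 against 66.1 FPKM.

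Among the lists that stand for other features of the samples, ribosomal protein genes and histone and cell cycle genes lay outside the central 95% of random lists, and the markers of other tissues and the circadian clock inside. Cytosolic ribosomal protein genes, fixed as a control list, had a median of 0.52 (0.28 after centring), above all random lists, although 8 of 284 were higher and 2 lower by a log2 ratio of 1 (5 and 4 after centring). A control list thus lay outside as well, so such a place is not particular to lists tied to the treatment. The glutathione S-transferase median of 0.49 (0.27 after centring) was no larger than that of this control list. The L38 gene GRMZM2G069594 had 18.5 against 4.89 FPKM and the L14/L17/L23-family gene GRMZM2G454085 7.11 against 22.1 FPKM. Histone and cell cycle genes, markers of dividing tissue, had a median of 0.12 (-0.076 after centring), below the central 95% of random lists, a place lost with a minimum of 5 FPKM (percentile 10.8), with 2 of 121 higher and 2 lower (1 and 3 after centring). Among them GRMZM2G018820, caught by its annotation as related to a cyclin-dependent kinase and not itself a cyclin, had 2.72 against 15.4 FPKM and a histone H3 gene (GRMZM2G171387) 74.9 against 39.9 FPKM. Markers of seed, pollen or root had a median of 0.40 (0.18 after centring) at percentile 97.3 over 18 genes, 1 higher and 2 lower, and the pollen Ole e 1 family gene GRMZM2G073969 had 53.6 against 332 FPKM in the control. The circadian clock list of 21 genes had 2 higher and 2 lower (median 0.04, -0.14 with 1 higher and 4 lower after centring, percentile 5.16). In it bHLH118 (GRMZM2G061906) had 86.4 against 41.0 FPKM. Like GRMZM2G017586, it was caught by the name of its family (CLOCK/ARNT/BMAL/PAS), which does not show that it is a clock gene. The CCA1-related genes GRMZM2G175265 and GRMZM2G474769, which share 1 reference gene, had 40.9 against 74.8 and 46.9 against 83.8 FPKM. Over the 34 lists with a percentile, 9 lay below and 6 above the central 95% of random lists, and after centring 12 lay below and 6 above. Lists of genes drawn at random would give 1.7 outside, but members of a real list can vary together between any 2 pools. The excess over 1.7 is therefore no evidence of a treatment effect. Without a minimum only the photosystem, chlorophyll synthesis, ribosomal protein and WRKY lists kept their place outside.

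**Figure D2:**
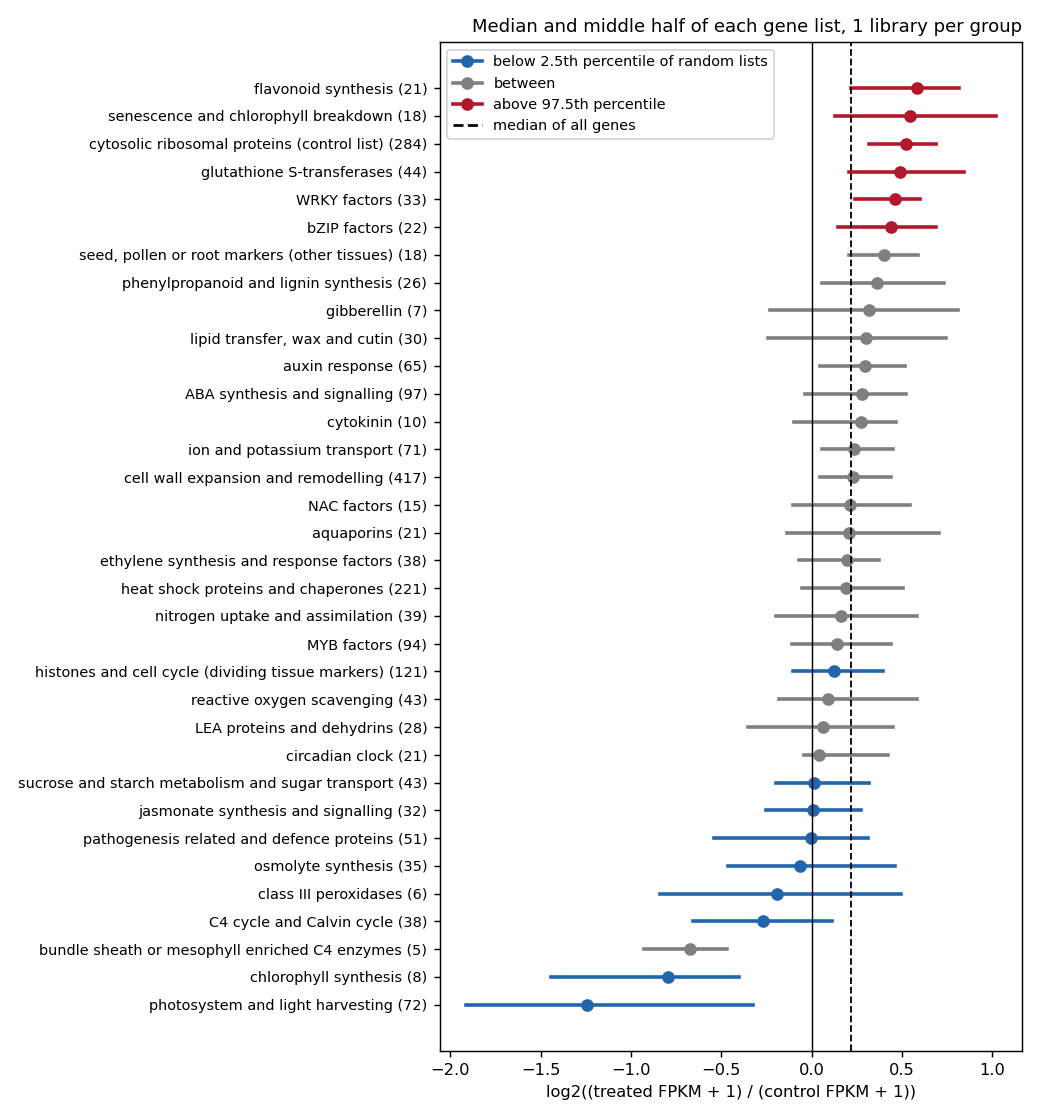
Median (point) and interquartile range (line) of log2((treated FPKM + 1)/(control FPKM + 1)) for the 34 gene lists with at least 5 members, numbers of members in parentheses, coloured by the percentile of the median among 10000 random lists; the dashed line is the median of all genes, 0.22. The photosystem list is lowest at -1.24 and the flavonoid list highest at 0.58.

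The authors' own comparison of the same 2 libraries listed more genes as lower than as higher. The authors' deposited table at a p of at most 0.05 held 631 lower and 380 higher genes, and the shorter one at a p of at most 0.01 held 273 and 139. As significant, the authors' deposited table marked 86 lower and 36 higher genes, which is the number with a q of at most 0.05. The smallest absolute log2 fold change in the longer lists was 1.001 for the lower and 1.037 for the higher genes. All 631 lower and all 380 higher genes had the listed direction in the library tables (100%). The lists come from these same 2 libraries, so this share was nearly fixed in advance and is no separate support. With the pseudocount, 327 and 331 of the genes passed a log2 ratio of 1 in the library tables. One library was at 0 for 77 of the lower and 39 of the higher genes in the authors' deposited table. The photosystem list had 36 members among the lower genes of the authors' deposited table, 10 of them significant, and 1 among the higher genes.

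Of the highest annotated genes, the authors' deposited table gave PPCK1 (GRMZM2G178074), the kinase gene that regulates phosphoenolpyruvate carboxylase, as higher with a log2 fold change of 1.31 and a q of 0.759, and the library tables gave 33.4 and 102 FPKM. The cysteine protease gene GRMZM2G166281, annotated as actinidain, had a log2 fold change of 1.51 and a q of 0.694 in the authors' deposited table, and 28.3 and 97.2 FPKM in the library tables. The third was the organelle-type psbE locus GRMZM2G108467, with 3.37 and a q of 0.00995 in the authors' deposited table. On the lower side were the antenna and photosystem I genes GRMZM2G033885 (Lhcb4), GRMZM2G092311 and GRMZM2G080107, to which the authors' deposited table gave log2 fold changes of -2.76, -1.73 and -1.80 with q-values of 0.53, 0.798 and 0.674. CKX10 (GRMZM2G348452) had a log2 fold change of -4.22 and a q of 0.00995 in the authors' deposited table. Over 895 genes above 0 in both libraries, the log2 fold change in the authors' deposited table differed from that of the library tables by a median of -0.27, against the treated library.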

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

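Matching lists by description only and leaving out the organelle-type loci were chosen after seeing the data, and the other alternatives were set before. No paired analysis was possible because each group has 1 library and no test was run. With a pseudocount of 0.1, 1361 genes were higher and 657 lower, and the median of the ribosomal protein list was 0.58. A pseudocount of 5 gave 154 higher and 162 lower genes and a ribosomal median of 0.36. A minimum of 5 FPKM left 400 higher and 242 lower genes, since fewer genes were counted, and a log2 ratio of at least 2 left 55 and 94. Centring on the median gene gave 332 higher genes and medians of -1.51 for the photosystem list, 0.27 for glutathione S-transferases and 0.28 for ribosomal proteins, which follows from the shift it removes. Without a minimum the counts were 604 and 410 by construction, but the lists took in silent genes and their medians were -0.94 (photosystem), 0 (glutathione S-transferases), 0.061 (senescence) and 0.35 (ribosomal proteins), with 3 lists below and 3 above the central 95%. There the glutathione S-transferase list, with its median of 0, lay inside, and the percentiles were 79.85 for senescence, 8.88 for carbon fixation and 47.9 for flavonoids, both with a median of 0. The other lists that lost their place outside were sugar metabolism (11.25), osmolytes (21.4), jasmonate (3.10), defence proteins (49.55), histones and cell cycle (30.3), class III peroxidases (median 0) and bZIP factors (89.05), while the cell wall list (99.05) and the C4 cell type list (0.95) lay outside. The photosystem list kept a negative median at the lowest percentile of random lists under each of the 10 alternatives run for it. Among the authors' lists a q of at most 0.01 kept 27 higher and 66 lower genes, and a log2 ratio of 1 in the library tables kept 87.1% and 51.8% of the genes listed as higher and lower.

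Medians close to 0 changed sign. With a minimum of 5 FPKM they were 0.16 for osmolytes, -0.028 for sugar metabolism and 0.013 for defence proteins. Centring gave -0.19 for sugar metabolism, -0.15 for jasmonate and -0.076 for histones and cell cycle. A common sum over nuclear genes gave 0.016 for defence proteins, and matching by description only gave -0.042 for jasmonate. Beyond the shift, the cause was not tested. Keeping only status OK removed no measured gene, so that it tests nothing. Depth limits low genes most, since the median distance from the value to the upper bound is 20.2% and 21.6% over genes between 1 and 10 FPKM and 8.65% and 9.75% above.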

Other observations

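Further light-harvesting and light-stress genes, chosen after their values were seen, differed in both directions, with the treated value set against that of the control. The LHCA2-type antenna genes GRMZM2G038519 and GRMZM2G072280, which the photosystem list's pattern did not match, were lower in the treated library with 74.7 against 337 FPKM and 57.1 against 210.1 FPKM, as was the thylakoid curvature protein gene GRMZM2G177508 with 29.9 against 82.8 FPKM. The early light-induced protein genes GRMZM2G355752 and GRMZM2G425728, whose products bind chlorophyll under light stress, went the other way with 531 against 149.9 FPKM and 237 against 84.0 FPKM. The gene of the photosystem II 22 kDa protein (GRMZM2G077333), which acts in the dissipation of excess light, had 891 against 683 FPKM, a log2 ratio of 0.38 that is 0.12 after centring.

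Other single genes with large differences, also chosen after their values were seen, are of several kinds. Among the higher ones an aspartate aminotransferase gene (GRMZM2G146677) had 331 against 110.6 FPKM, the asparaginase genes GRMZM2G082032 and GRMZM2G531230 had 84.8 against 32.3 and 73.0 against 27.3 FPKM (uncertain singly, since they share 1 reference gene), and a vacuolar processing enzyme gene (GRMZM2G093032) had 264 against 92.6 FPKM. Among the lower ones were a ribonuclease T2 gene (GRMZM2G158394) with 17.4 against 217 FPKM, the germin-like gene glp1 (GRMZM2G064096) with 4.85 against 76.9 FPKM, and an aminotransferase gene of another subgroup (GRMZM5G828630) with 14.9 against 138 FPKM.

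In the paragraphs that follow, the tests of read exchange and of transcript yield for the photosystem genes were set before their results were seen, and the others after. The lower photosystem values are the first pattern. Over the 62 members that are not organelle-type loci the summed FPKM was 16120 in the control and 8177 in the treated library, 1.25 below the median gene on the log2 scale (-1.25), which argues against reads that only moved between near-identical copies. Random lists were matched on broad bins of mean FPKM and on implied fragments per FPKM, meant as a stand-in for transcript length. The medians of these lists were no lower than -0.070 against -1.32 for the members. Interval width does not follow length alone, however. In the control, pep1 had 1747 FPKM (1737 to 1757) and me3 944 FPKM (907 to 981) at loci of similar span. The match on length is therefore loose, and a lower yield of short transcripts stays open. The highest bin of mean FPKM also took in genes far less abundant than most members, so a lower yield of the most abundant transcripts stays open. Among all genes at 100 FPKM or more, members included, 20 were higher and 55 lower. A different time of day at harvest stays open, since 2 of 3 CCA1-related genes lay below the median gene by up to 1.14 (-1.14) while the third and both GIGANTEA genes lay within -0.31 of it. The treatment and any other difference between the 2 pools cannot be told apart with 1 library each, so a response to the extract remains a hypothesis.

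The second pattern is a set of 43 loci at 10 FPKM or more in 1 library with an absolute log2 ratio of at least 3, 29 of them lower and 14 higher. Organelle-type loci made up 30.2% of the set (13 of 43) against 1.03% of the other 3998 genes at 10 FPKM or more. The grouping was made after many of these loci had been seen among the largest differences, so the shares describe the set and are no separate test, and whether organelle reads were placed at other nuclear copies stays open. Among the other 30 loci, reads moved to a copy with the same reference gene can be traced for 2, the chlorophyll a/b binding protein genes GRMZM2G414192 and GRMZM2G018627, whose sum was 60.1 FPKM in the control and 32.7 FPKM in the treated library. Of the remaining ones, 12 have no reference gene and could not be searched, and for 16 no other locus has the same reference gene.

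The third pattern is the split of higher against lower genes, 604 and 410 in the library tables against 380 and 631 in the authors' deposited lists. The authors' comparison is offset from the library tables by -0.27 against the treated library, which matches the median log2 ratio of 0.27 that the library tables show, so the scaling of the library tables is a candidate source of the different split. The criterion differs too. The authors' lists go by a p of at most 0.05, and no listed gene has an absolute log2 fold change below 1 on the authors' own scale. On the scale of the library tables with a pseudocount of 1, 331 of the genes listed as higher and 327 of those listed as lower pass a log2 ratio of 1. A few genes taking most of the FPKM could account for part of the 0.27. Without the 10 highest genes 0.19 was left, and without these and the photosystem list 0.12, so they are not the whole of it.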
